A study of Mus musculus with 10 samples.

How the data were processed

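Spleens had been pressed through a 40 µm strainer and the cells loaded for 10x Genomics 3' v3.1 single-cell RNA sequencing, per the labels' protocols. The deposited matrices held integer counts of UMIs for called barcodes, made by Cell Ranger 7.0.1 per the file headers, and the mouse reference was mm10 (GRCm38) per the submitters' processing notes. They held 32287 features, among them the added sequences luc1 and luc2. Of these features 32235 matched an identifier of GENCODE vM21 (GRCm38), from which gene names, identifiers and positions were taken. The number of barcodes shared between libraries implied a list of 722268 possible barcodes (median of 45 library pairs, 653427 to 809004). The kit is given as the labels state it. Whether a list of that size belongs to that kit was not resolved, so the kit stays in doubt. No reads were used here. Some results for single genes are not reported here.

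Barcodes with at least 500 UMIs, at least 200 genes and at most 20% mitochondrial UMIs were kept. Counts were scaled per barcode and log-transformed, and 2000 variable genes, 40 principal components and 20 neighbours gave 65 Leiden clusters at resolution 1.5 with seed 0 (scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9). Classes were named from marker genes of each cluster, so a name ends in "-like" in the text. Clusters of few UMIs without markers (background), clusters with markers of more than 1 lineage, clusters of nuclear-like barcodes and the 341 cells of clusters under 50 cells were left out. The background and nuclear-like groups were set apart after the clusters were seen. Doublets were ranked by scrublet score and left out up to the expected rate of 0.8% per 1000 barcodes, also a choice made after the scores were seen, since scrublet's own threshold called 0.005% to 5.84% of barcodes. The depth per library and per cell stands at the start of the report.

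UMIs were summed per library and class, and genes were tested in CD4 T-like, CD8 T-like, B-like and neutrophil-like cells with edgeR 4.0.16 (quasi-likelihood, TMM scaling, two-sided, R 4.3.3) on the 9 treated or vehicle libraries in 1 fit. The adjusted p threshold was 0.05 (Benjamini-Hochberg). Levels of single genes and list means within a class are UMIs scaled to the TMM-adjusted total of the class (CPM). Sums over genes, levels over the whole spleen and levels set beside the healthy library used totals without TMM. The immature myeloid-like class had too few cells in treated libraries for gene tests. Gene lists, 26 in number, were tested with camera of limma 3.58.1 at a preset correlation of 0.01 where at least 5 genes were tested, and also counted gene by gene. They cover WEHI-3 insertion genes, primary granule genes, respiratory chain, mitochondrial mRNAs, mitochondrial and cytosolic ribosomal proteins, integrated stress response, mitochondrial proteases, tricarboxylic acid cycle, glycolysis, cholesterol synthesis, p53 targets, cell cycle, interferon responses, NF-kB, MHC class II, T cell states, dissociation and markers of other cells. Class shares were tested with edgeR on cell numbers with the total as offset, and exact two-sided permutation tests were run on single values. With 3 against 3 libraries the smallest exact p is 0.1. The healthy library was described with exact Poisson and binomial intervals, and its list medians were set against 10000 random lists of like level with a pseudocount of 1 CPM, over all genes tested in the class. Single genes were named where they had at least 50 CPM in the healthy library or on average with vehicle. The share of RNA of other cells in a class was summed over the other classes of at least 50 cells in the library, each as the median ratio of up to 20 markers. A marker had at least 200 CPM in its class and over 20 times the level of the receiving class, in the vehicle libraries. Markers were first chosen from the IMP125 library itself, and the choice was changed after those values were seen.

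The gene lists, the comparisons, the alternatives and the naming rule were fixed before the data were examined. The rule named the 5 highest and lowest genes past the threshold in T-like classes and 3 in the others, at a level of at least 20 CPM, at 0.5 or more of the level over all cells and with no overlap of libraries between groups, leaving out segments of antigen receptors, haemoglobins, ribosomal proteins, mitochondrial genes and unnamed gene models. It added up to 4 members per list and Il3, Hoxb8, Clpp, Clpx and Cdkn1a. Alternatives were the replicate number as a block, each library left out, doublets kept, stricter cells (1000 UMIs, 500 genes, 10% mitochondrial), DESeq2 1.42.0, library size scaling, no filter on low counts, only the 6 libraries compared, a UMI gate for T cells, genes low in the class left out, an estimated correlation, other totals for shares and a pseudocount of 5 CPM. Another 2, shares of all kept barcodes and sums over every kept barcode, were chosen after seeing the data.

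The steps were tested on simulated data. With 3 against 3 libraries edgeR found 57.6%, 54.1%, 54.5% and 12.5% of 2-fold changes and 87.8%, 88.8%, 89.7% and 83.0% of 4-fold changes in CD4 T-like, CD8 T-like, B-like and neutrophil-like cells. Camera found the raised list in each class and called 0 of the unchanged lists. The simulated genes were drawn independently of each other, so this test could not show false calls from genes that vary together. Random lists lay outside the 95% interval of the percentile test in 7% of 200 draws. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.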

Results

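Single-cell transcriptomes were measured in spleen cells of BALB/c mice, most of which carried a syngeneic leukaemia. WEHI-3, a mouse myelomonocytic leukaemia line that here also carried luciferase, had been injected into a vein. From day 9 the mice received vehicle, doxorubicin, an anthracycline that damages DNA through topoisomerase II, or IMP125, a compound known here only by its code name. IMP125 was given at 5 mg/kg, and both drugs in 4 intravenous doses; the labels give no dose for doxorubicin. The data held 3 vehicle, 3 doxorubicin and 3 IMP125 libraries and 1 library of a healthy mouse. The title of the series names the mitochondrial protease ClpP, the depletion of leukaemia cells, the function of T cells and metabolism, and the comparisons below follow those subjects.

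The libraries held 11487 to 19836 barcodes and 56192071 (healthy) to 109953902 (vehicle 3) unique molecular identifiers (UMIs). After filters, 8469 to 12526 cells per library entered the comparisons, with a median of 2856 to 4663 UMIs per cell. Barcodes with few UMIs and no markers of a cell type, called background barcodes here, made up 30.5% to 49.1% of the barcodes of the healthy, vehicle and doxorubicin libraries. In the IMP125 libraries they made up 1.2%, 0.143% and 2.26%. The median share of mitochondrial UMIs per cell was 2.17% to 2.5% in the IMP125 libraries and 1.28% to 1.61% in the others. All values are mean ± SD over 3 libraries per group unless stated. Levels of single genes within a class are UMIs scaled to the TMM-adjusted total of the class (CPM). Sums over genes, levels over the whole spleen and levels set beside the healthy library used plain totals, so a vehicle level can differ between passages.

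The first comparison set IMP125 against vehicle, and asked what the treatment left of the leukaemia. Immature myeloid-like cells, the class that carried the markers of WEHI-3 cells, made up 5.92% ± 4.28 of the cells analysed with vehicle (719, 121 and 1026 cells). With IMP125 they made up 0.0451% ± 0.0210 (2, 7 and 6 cells). The share fell by 6.98 on the log2 scale (SE 0.97, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over classes, adjusted p = 0.0017), a 126-fold lower share. The exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries can give. The healthy spleen held 0 such cells of 8469, with a 95% exact binomial interval up to 0.04355%.

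Transcripts of Il3 and Hoxb8, genes activated by proviral insertion in WEHI-3 cells, were also summed without regard to class. Both were among the markers listed for the immature myeloid-like class, and its cells are in the sum. This reading of the leukaemia is therefore not separate from the share of that class. The cells summed leave out background barcodes. Those held 684 of 1552, 276 of 463 and 1067 of 2274 barcodes with Hoxb8 in vehicle 1, 2 and 3, and 0 in each IMP125 library. Summed over all cells analysed, Hoxb8 (ENSMUSG00000056648, GRCm38 chromosome 11, 96281905 to 96285315) was at 54.1 ± 36.7 CPM with vehicle and 0.922 ± 0.584 CPM with IMP125, 53.9-fold lower (edgeR adjusted p = 0.038). Il3 (ENSMUSG00000018914, GRCm38 chromosome 11, 54265303 to 54267277) was at 1.75 ± 1.59 CPM and 0.0392 ± 0.0292 CPM, 39.1-fold lower (edgeR adjusted p = 0.047, 426 and 8 UMIs in all). The transcript of the added sequence luc2 was seen in 133, 14 and 91 barcodes of the vehicle libraries and in 1, 1 and 0 of the IMP125 libraries. In vehicle 1, 2 and 3 it was found in 15.6%, 9.63% and 6.85% of the barcodes classed as immature myeloid-like and in 0, 0 and 1 of those classed as B-like, at medians of 13060 to 33870 and 2178 to 3638 UMIs. Transcripts of the neutrophil primary granule genes Mpo, Elane, Prtn3, Ctsg and Ms4a3 were 5.91-fold to 10.9-fold lower over the whole spleen, and none passed the test (edgeR adjusted p = 0.077 to 0.15; 0 of 5 genes against an unadjusted p under 0.05 for all 5). Leaving out 1 library ended the calls of Hoxb8 and Il3 in 8 of 9 cases (edgeR adjusted p of up to 0.151 and 0.156). It brought each of the 5 granule genes past the threshold in 1 of 9 cases (lowest edgeR adjusted p = 0.00449 to 0.013).

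**Figure D1:**
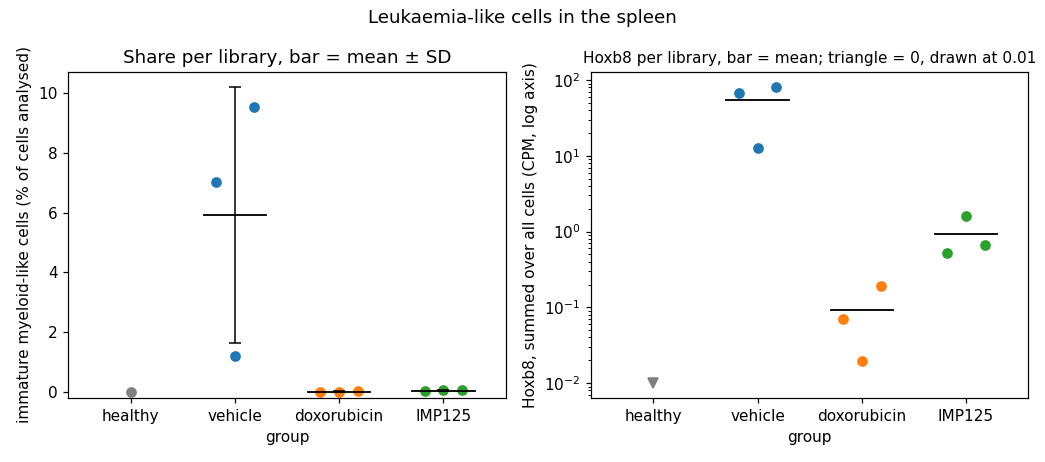
Left, the share of immature myeloid-like cells among cells analysed (%, linear axis) in each library, by group, with the mean ± SD; the vehicle libraries lie at 1.2% to 9.54%. Right, Hoxb8 summed over all cells (CPM, log axis) in each library with the mean, a triangle marking 0 in the healthy library.

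None of the other classes passed the test for IMP125 against vehicle. CD8 T-like cells made up 13.4% ± 3.42 against 8.32% ± 3.21 (log2 difference 0.69, SE 0.33, edgeR adjusted p = 0.14) and CD4 T-like cells 18.1% ± 5.94 against 13.6% ± 2.28 (log2 difference 0.41, SE 0.29, edgeR adjusted p = 0.30). Leaving out vehicle 2 brought the CD8 T-like share past the threshold (log2 difference 1.05, edgeR adjusted p = 0.024). B-like cells made up 45.4% ± 5.81 against 36.8% ± 7.43 (edgeR adjusted p = 0.31) and neutrophil-like cells 1.77% ± 0.651 against 6.05% ± 4.63 (edgeR adjusted p = 0.11). The neutrophil-like share passed without vehicle 2 (log2 difference -2.27, edgeR adjusted p = 0.0022). These shares are of cells analysed; the background barcodes, which differed between the groups as given above, are not in them. As shares of all kept barcodes, an alternative chosen after seeing the data, B-like, CD4 T-like and CD8 T-like cells passed with IMP125 (log2 differences 0.98, 1.09 and 1.37, edgeR adjusted p = 0.018, 0.025 and 0.018). As shares of cells analysed the log2 differences were 0.30, 0.41 and 0.69. The larger total takes in the background barcodes, which were few with IMP125. It therefore raises the share of every class there, and these passes do not show a change of the lymphocytes.

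**Figure D2:**
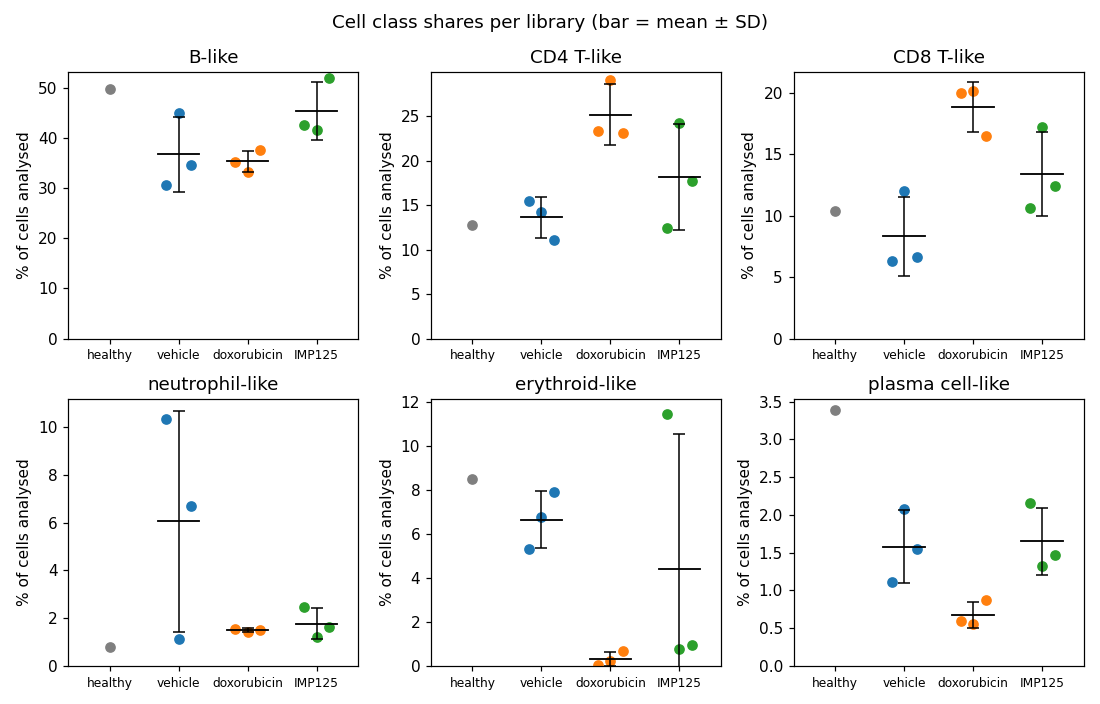
Shares of 6 cell classes among cells analysed (%, linear axes from 0) in each library, by group, with the mean ± SD; the healthy group has 1 library and no bar. CD4 T-like and CD8 T-like shares were highest with doxorubicin, at means of 25.2% and 18.9%.

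Within the cell classes, interferon-stimulated genes were higher with IMP125 than with vehicle in T-like, B-like and neutrophil-like cells. In neutrophil-like cells Ifit3 (ENSMUSG00000074896, GRCm38 chromosome 19, 34583531 to 34588731), an antiviral protein induced by interferon, rose from 0.782 ± 0.720 to 493 ± 220 CPM (log2 fold change 10.01, SE 0.77, edgeR adjusted p = 9.2e-05). Rsad2, the antiviral enzyme viperin, rose from 11.5 ± 7.25 to 1964 ± 940 CPM (log2 fold change 7.51, edgeR adjusted p = 0.00011) and Gbp2, a guanylate-binding protein, from 11.1 ± 5.48 to 422 ± 235 CPM (edgeR adjusted p = 0.00037). In CD4 T-like cells Isg15, a ubiquitin-like modifier, rose from 44.8 ± 1.45 to 554 ± 331 CPM (log2 fold change 3.63, SE 0.48, edgeR adjusted p = 0.032) and Rtp4 from 19 ± 8.15 to 236 ± 110 CPM (edgeR adjusted p = 0.020). The largest increases in CD4 T-like cells were those of Ifit3b, Ifit3, Ifi44, Oas2 and Ifit1 (log2 fold changes 4.54 to 6.64, edgeR adjusted p = 0.041 to 0.049). In CD8 T-like cells Ifi27l2a rose from 177 ± 89.6 to 1968 ± 819 CPM, beside Rtp4, Samd9l and Adar (log2 fold changes 1.38 to 3.86, edgeR adjusted p = 0.024 to 0.044). In B-like cells Ifit3b, Oas3 and Ifit1 had the largest increases (log2 fold changes 7.01 to 8.02, edgeR adjusted p = 0.025 to 0.039).

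Of the 26 genes of the type I interferon list, 14 rose in CD4 T-like, 2 in CD8 T-like, 23 in B-like and 25 in neutrophil-like cells, and 0 fell. Adjusted over the list alone, all 26 rose in each of the 4 classes. The list passed limma's camera in each class (median log2 fold change 3.58, 3.55, 4.99 and 4.05; camera adjusted p = 8.0e-30, 3.2e-26, 3.0e-25 and 3.9e-48). It did not pass camera when the correlation was estimated (adjusted p = 0.195, 0.224, 0.203 and 0.142 with an estimated correlation). Of the interferon gamma list, 2 of 24, 0 of 24, 7 of 24 and 13 of 21 genes rose in the same order of classes, and 21, 21, 23 and 20 adjusted over the list alone. In CD8 T-like cells, where edgeR called 0 of its genes, 21 had an unadjusted p under 0.05 and DESeq2 called 14. This list also passed camera (camera adjusted p = 4.6e-21, 3.8e-18, 8.5e-15 and 8.2e-24; adjusted p = 0.195, 0.224, 0.263 and 0.164 with an estimated correlation).

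The 3 IMP125 libraries differed in these genes. The type I interferon list summed to 7904, 12905 and 3943 CPM in the B-like cells of IMP125 1, 2 and 3, against 280 to 800 CPM with vehicle. Different clusters held most of a class in the groups. Cluster 4 of the B-like cells held 64.5%, 94.2% and 14.9% of those of IMP125 1, 2 and 3 and at most 1.40% elsewhere. Cluster 14 of the CD4 T-like cells held 57.1%, 80.2% and 13.9%, and cluster 20 of the CD8 T-like cells 75.5%, 87.9% and 12.1%. The leading genes of these clusters include interferon-stimulated genes, such as Ifit3 in cluster 4 and Ifit1 in clusters 14 and 20. Their shares therefore restate the difference in these genes and are no separate finding. In vehicle 1, cluster 36 held 76.7% of the neutrophil-like and cluster 11 59.5% of the B-like cells. The share of background barcodes, 0.143% to 2.26% with IMP125 against 37.6% to 39.2% with vehicle, separated the same libraries as these genes.

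**Figure D3:**
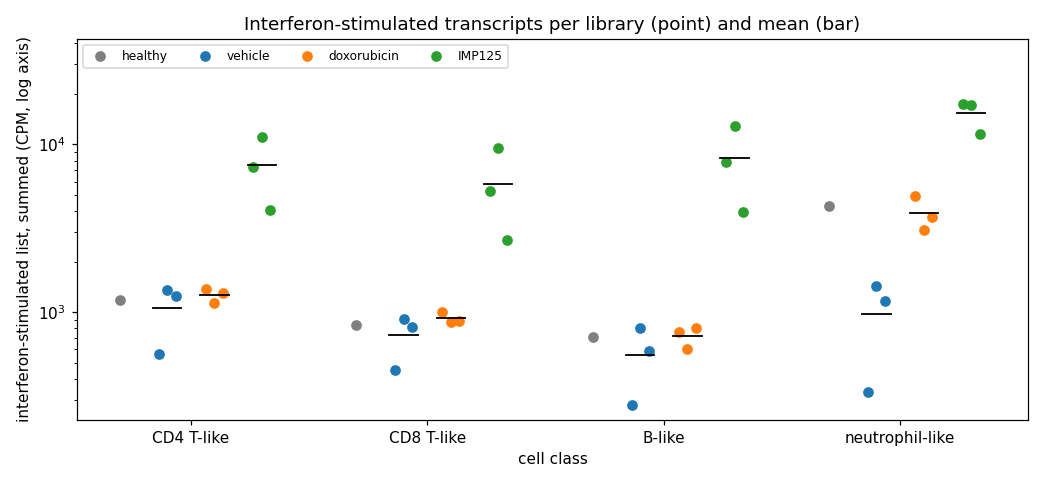
The type I interferon list summed in 4 cell classes (CPM, log axis) for each library, coloured by group, with a bar at each group's mean. All 3 IMP125 libraries lie above every other library in each class, and among B-like cells at 3943 to 12905 CPM.

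Transcripts of the mitochondrial genome were the other large change with IMP125. In CD4 T-like cells mt-Nd2 (ENSMUSG00000064345, GRCm38 chromosome M, 3914 to 4951), a subunit of respiratory complex I, rose from 543 ± 56.5 to 2360 ± 285 CPM (log2 fold change 2.12, SE 0.12, edgeR adjusted p = 2.6e-05). The complex I subunits mt-Nd1, mt-Nd4 and mt-Nd5 rose there by 1.88 to 1.97 on the log2 scale (edgeR adjusted p = 2.6e-05 to 4.6e-05). In CD8 T-like cells the 4 genes rose by 1.61 to 1.76 (edgeR adjusted p = 9.5e-05 to 0.00057) and in B-like cells by 1.81 to 1.94 (edgeR adjusted p = 0.0010). In neutrophil-like cells mt-Nd2, mt-Nd1, mt-Nd3 and mt-Nd5 rose by 1.23 to 1.69 (edgeR adjusted p = 0.021 to 0.034). Of the 13 mitochondrially encoded mRNAs, 9, 8, 10 and 6 rose in CD4 T-like, CD8 T-like, B-like and neutrophil-like cells, and 12, 9, 10 and 8 adjusted over the list alone. The list passed camera (camera adjusted p = 1.4e-27, 5.4e-24, 9.1e-20 and 2.0e-09; adjusted p = 0.0968, 0.117, 0.18 and 0.509 with an estimated correlation).

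The increase differed between transcripts, as sums over groups of genes chosen after their values were seen show. In B-like cells mt-Nd1, mt-Nd2, mt-Nd4 and mt-Nd5 summed to 6869 ± 1075 CPM against 2143 ± 90.9 CPM, 3.18-fold higher. The cytochrome genes mt-Co1, mt-Co2, mt-Co3 and mt-Cytb summed to 12321 ± 296 against 11074 ± 1658 CPM, 1.12-fold higher. Over classes the complex I sum was 3.53-fold higher in CD4 T-like, 3.25-fold in regulatory T-like, 1.93-fold in NK-like, 1.27-fold in monocyte-like and 1.23-fold in erythroid-like cells. The exact two-sided permutation p of the complex I sum was 0.1, the smallest possible, in B-like, CD4 T-like and CD8 T-like cells. Nuclear genes of the respiratory chain moved little. Of 77 and 78 such genes 0 passed edgeR in CD4 T-like and CD8 T-like cells (7 and 7 at an unadjusted p under 0.05; 1 and 0 by DESeq2), with medians of -0.04 and -0.03 on the log2 scale. Camera called the list lower in CD4 T-like cells (adjusted p = 0.025; adjusted p = 0.717 with an estimated correlation). It was called higher in B-like cells (median 0.08, camera adjusted p = 0.027; adjusted p = 0.693 with an estimated correlation). Camera did not call it in CD8 T-like or neutrophil-like cells (adjusted p = 0.255 and 0.137). The call in CD4 T-like cells ended without vehicle 3 (mean 0.0089 instead of -0.054, camera adjusted p = 0.955) or IMP125 2 (0.128). That in B-like cells ended without vehicle 2 or IMP125 1 (camera adjusted p = 0.655 and 0.497).

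**Figure D4:**
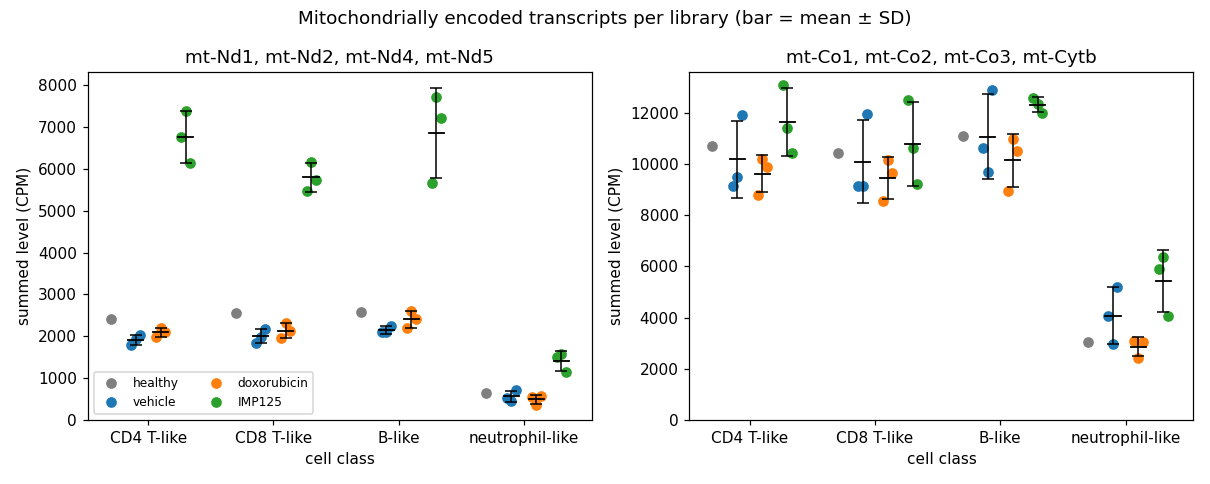
Summed levels (CPM, linear axes from 0) of 4 mitochondrially encoded complex I genes (left) and 4 cytochrome genes (right) in 4 cell classes, one point per library coloured by group, with the mean ± SD. In B-like cells the complex I sum was 3.18-fold higher with IMP125 than with vehicle and the cytochrome sum 1.12-fold higher.

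Clpp (ENSMUSG00000002660, GRCm38 chromosome 17, 56990305 to 56996188) and Clpx, the proteolytic and the unfolding subunit of the ClpXP protease, did not pass the test with IMP125 against vehicle. Clpp was at 46.9 ± 4.10 against 52.4 ± 8.57 CPM in CD4 T-like cells (edgeR adjusted p = 0.68). In B-like cells it was at 49.7 ± 4.64 against 54 ± 4.95 CPM (edgeR adjusted p = 0.61). Clpx was at 27.2 ± 2.86 against 27.7 ± 9.52 CPM and at 25.1 ± 1.55 against 32.1 ± 7.30 CPM (edgeR adjusted p = 0.97 and 0.26). Camera called none of the 4 classes for the mitochondrial proteases and chaperones (camera adjusted p = 0.077 to 0.532) or the tricarboxylic acid cycle (camera adjusted p = 0.249 to 0.644). For glycolysis it called B-like cells alone (median log2 fold change 0.19, camera adjusted p = 0.0053; adjusted p = 0.444 with an estimated correlation), where Gapdh rose from 236 ± 18.2 to 339 ± 15.4 CPM (edgeR adjusted p = 0.036). Mitochondrial ribosomal proteins were called in B-like cells (median 0.11, camera adjusted p = 0.0040; adjusted p = 0.512 with an estimated correlation) and neutrophil-like cells (camera adjusted p = 0.014; adjusted p = 0.934 with an estimated correlation). Cytosolic ribosomal proteins were called in all 4 classes, at medians of 0.12 to 0.22 (camera adjusted p = 2.9e-14 to 0.0096; adjusted p = 0.398 to 0.934 with an estimated correlation). The glycolysis call ended without vehicle 1 (camera adjusted p = 0.11), and that of mitochondrial ribosomal proteins in B-like cells without vehicle 2 (camera adjusted p = 0.36). In neutrophil-like cells both ribosomal lists lost their calls without vehicle 2, vehicle 3 or IMP125 1 (camera adjusted p = 0.0579 to 0.579). The mean of the cytosolic list moved from 0.164 to 0.0961 in CD4 T-like cells without IMP125 3. In B-like cells it moved from 0.169 to 0.0726 without vehicle 2 and to 0.0628 without IMP125 2.

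In T-like cells the lists of T cell state moved less than the interferon list. Of the exhaustion genes, which include inhibitory receptors, 0 of 14 in CD4 T-like and 0 of 15 in CD8 T-like cells passed edgeR (2 and 2 at an unadjusted p under 0.05; 0 and 0 by DESeq2; 0 and 1 adjusted over the list alone). Camera gave adjusted p = 0.158 and 0.739 for them, and 0.823 and 0.142 for the effector genes. The activation list was higher in CD4 T-like (median log2 fold change 0.42, camera adjusted p = 0.00023), CD8 T-like (0.47, camera adjusted p = 0.0015) and B-like cells (0.60, camera adjusted p = 8.4e-06), with adjusted p = 0.195, 0.386 and 0.18 with an estimated correlation. Within it Nr4a1, an immediate early nuclear receptor, rose from 295 ± 53.2 to 516 ± 52 CPM in CD4 T-like cells (log2 fold change 0.81, SE 0.15, edgeR adjusted p = 0.049). Nr4a1 is also in the list of dissociation and immediate early genes, called higher in the same 3 classes (camera adjusted p = 4.5e-06, 6.3e-06 and 8.4e-06; adjusted p = 0.195, 0.386 and 0.18 with an estimated correlation). Pim1, a cytokine-induced kinase, rose in CD8 T-like cells from 196 ± 12.9 to 406 ± 57 CPM (log2 fold change 1.05, SE 0.15, edgeR adjusted p = 0.028). The naive and memory list was called in CD4 T-like cells (median 0.13, camera adjusted p = 0.047; adjusted p = 0.195 with an estimated correlation) and not in CD8 T-like cells (camera adjusted p = 0.151). These calls depended on single libraries. Without vehicle 1 the mean of the activation list moved from 0.45 to 0.27 in CD4 T-like and from 0.46 to 0.23 in CD8 T-like cells, where the call ended (camera adjusted p = 0.0704). The mean of the dissociation list in CD8 T-like cells moved from 0.53 to 0.22. The naive and memory call ended without vehicle 1, IMP125 2 or IMP125 3 (camera adjusted p = 0.116 to 0.141). Camera called exhaustion genes higher in CD4 T-like cells without vehicle 2 or IMP125 2 (adjusted p = 0.00974 and 0.00707). It called effector genes higher in CD8 T-like cells without vehicle 2, vehicle 3 or IMP125 3 (adjusted p = 0.00523, 0.0449 and 0.0332). Txndc15 was the 1 gene past the naming rule that fell in CD4 T-like cells, from 33.8 ± 0.765 to 22.1 ± 1.80 CPM (edgeR adjusted p = 0.049).

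Stress and sterol genes also moved with IMP125. In B-like cells Ddit3, the stress transcription factor CHOP, rose from 32.8 ± 1.60 to 57.1 ± 9.94 CPM (log2 fold change 0.80, SE 0.14, edgeR adjusted p = 0.030) and Atf3, which tissue dissociation also induces, from 39.9 ± 3.65 to 136 ± 30.8 CPM (log2 fold change 1.77, SE 0.16, edgeR adjusted p = 0.0021). The integrated stress response list was higher in CD4 T-like, CD8 T-like and B-like cells (median log2 fold change 0.24, 0.23 and 0.33; camera adjusted p = 0.038, 0.016 and 0.0022; adjusted p = 0.195, 0.224 and 0.311 with an estimated correlation). Adjusted over the list alone, 3, 4 and 4 of its 18, 16 and 19 genes rose and 1, 1 and 0 fell. Cholesterol synthesis was higher in CD4 T-like and B-like cells (median 0.41 and 0.53; camera adjusted p = 4.9e-06 and 4.9e-06; adjusted p = 0.195 and 0.18 with an estimated correlation). Of its 15 genes 6 and 9 rose when adjusted over the list alone. Over all genes tested, 3 of them rose in B-like cells. Cell cycle genes were called higher in B-like and neutrophil-like cells (median 0.58 and 0.85; camera adjusted p = 2.3e-06 and 2.5e-08; adjusted p = 0.445 and 0.834 with an estimated correlation). They were called lower in CD4 T-like and CD8 T-like cells (-0.33 and -0.39; camera adjusted p = 0.012 and 0.0074; adjusted p = 0.656 and 0.509 with an estimated correlation). The stress response calls in both T-like classes ended without vehicle 1, vehicle 2 or IMP125 3, and in CD4 T-like cells also without IMP125 2 (camera adjusted p = 0.0515 to 0.181). The lower cell cycle calls ended without IMP125 2 (camera adjusted p = 0.458 and 0.184), in CD4 T-like cells without vehicle 3 (0.108) and in CD8 T-like cells without IMP125 3 (0.0734). In B-like cells the mean of the stress list moved from 0.27 to 0.17 without vehicle 1, and that of the cell cycle list from 0.50 to 0.20 without IMP125 1. The make-up of the class differed: cluster 47 held 4.08%, 1.09% and 1.37% of the B-like cells of IMP125 1, 2 and 3 against 0.703% to 0.886% with vehicle.

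Among genes that fell with IMP125 in B-like cells were Atp1b1, a subunit of the sodium pump, from 52 ± 12.6 to 21.2 ± 2.62 CPM, and Bnip3l and Pink1, which act in the removal of mitochondria (log2 fold changes -1.29, -0.71 and -0.68; edgeR adjusted p = 0.025, 0.044 and 0.043). In neutrophil-like cells the lowest were Bcl2l15, Grk5 and Bcl2a1a (log2 fold changes -3.17, -2.48 and -1.96; edgeR adjusted p = 0.0039, 0.034 and 0.0050). Camera called the p53 target list in none of the 4 classes (adjusted p = 0.222 to 0.855), and its member Cdkn1a, an inhibitor of cyclin-dependent kinases, was at 27.3 ± 0.542 against 17.6 ± 4.19 CPM in CD4 T-like cells (edgeR adjusted p = 0.32). NF-kB targets were called in CD8 T-like cells alone (median 0.26, camera adjusted p = 0.00041; adjusted p = 0.224 with an estimated correlation). Genes of MHC class II were called in the 3 lymphocyte classes (medians 0.43 to 0.71, camera adjusted p = 0.0053 to 0.021; adjusted p = 0.512 to 0.567 with an estimated correlation). Vehicle 1 carried these calls: without it the means were 0.0381, 0.206 and 0.041 in CD4 T-like, CD8 T-like and B-like cells, against 0.724, 0.716 and 0.592 (camera adjusted p = 0.769, 0.417 and 0.536). Without vehicle 2 the means were 1.362, 1.62 and 0.9025. The calls also ended without IMP125 3 (camera adjusted p = 0.0515 to 0.0602), and in CD8 T-like cells without vehicle 3 or IMP125 1 (0.0712 and 0.0571). Transcripts of other cells moved too. Primary granule genes were lower in CD4 T-like, CD8 T-like and B-like cells (medians -3.23, -3.02 and -3.07; camera adjusted p = 6.2e-05, 1.2e-05 and 0.00023; adjusted p = 0.258, 0.282 and 0.311 with an estimated correlation). Erythroid genes were called lower in all 4 classes (camera adjusted p = 0.00020 to 0.0096; adjusted p = 0.398 to 0.846 with an estimated correlation). Only IMP125 2 and 3 were lower in the lymphocyte classes. In CD4 T-like cells IMP125 1 was at 4.41 (mean log2 CPM) against 3.25 to 3.64 with vehicle, and IMP125 2 and 3 at 0.879 and 1.97. The erythroid calls ended without IMP125 2 in CD4 T-like, CD8 T-like and neutrophil-like cells (camera adjusted p = 0.0838, 0.106 and 0.0813). They ended without IMP125 3 in B-like cells (camera adjusted p = 0.0719) and without vehicle 3 in neutrophil-like cells (0.0579). B and plasma cell genes were called higher in CD4 T-like and CD8 T-like cells (camera adjusted p = 0.042 and 0.012; adjusted p = 0.656 and 0.470 with an estimated correlation), while neutrophil and macrophage genes were not called in them (camera adjusted p = 0.222 to 0.828). Without vehicle 1 the mean of the B and plasma cell list turned from 0.608 to -0.146 in CD4 T-like cells and was 0.247 instead of 0.725 in CD8 T-like cells (camera adjusted p = 0.769 and 0.407). Without vehicle 2 the means were 1.094 and 1.471. These calls also ended without IMP125 1 (camera adjusted p = 0.156 and 0.0723), and in CD4 T-like cells without IMP125 3 (0.0515).

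Over all genes, edgeR called 61 higher and 2 lower of 11893 tested in CD4 T-like, 14 and 0 of 11509 in CD8 T-like, 178 and 44 of 13420 in B-like and 143 and 11 of 8135 in neutrophil-like cells. DESeq2 called 331, 309, 793 and 232 in all. At an unadjusted p under 0.05 there were 1479, 1385, 2402 and 1002 genes, and the groups did not overlap for 14.8%, 14.7%, 20.1% and 20.6% of genes, where chance gives 10%. The counts depended on single libraries. Without IMP125 3 they were 203, 209, 444 and 198, without IMP125 1 they were 6, 10, 12 and 102, and without vehicle 3 they were 7, 5, 7 and 109. Leaving out other libraries, doxorubicin libraries included, gave 9 to 47 in CD4 T-like, 6 to 29 in CD8 T-like and 12 to 230 in B-like cells.

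Doxorubicin was compared with vehicle as the reference treatment. Immature myeloid-like cells numbered 1, 0 and 2 in the doxorubicin libraries, a share of 0.00897% ± 0.00865. The share fell by 9.15 on the log2 scale (SE 1.12, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over classes, adjusted p = 0.00072), a 568-fold lower share, and the exact two-sided permutation p was 0.1. Hoxb8 over the whole spleen was at 0.0927 ± 0.0873 CPM, 574-fold lower than with vehicle, and Il3 at 0.0187 ± 0.0195 CPM, 90.9-fold lower on 3 UMIs (edgeR adjusted p = 0.026 for both). Mpo, Elane, Prtn3, Ctsg and Ms4a3 fell to 49.3-fold to 102-fold lower levels (edgeR adjusted p = 0.026 for each). Leaving out 1 library ended the calls of Hoxb8, Il3 and each of these 5 genes in 5 of 9 cases (edgeR adjusted p of up to 0.116 for each).

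Both T-like classes made up larger shares with doxorubicin than with vehicle. CD8 T-like cells were at 18.9% ± 2.04 against 8.32% ± 3.21 (log2 difference 1.18, SE 0.33, edgeR adjusted p = 0.023) and CD4 T-like cells at 25.2% ± 3.38 against 13.6% ± 2.28 (log2 difference 0.89, SE 0.30, edgeR adjusted p = 0.041). Erythroid-like cells fell from 6.64% ± 1.29 to 0.303% ± 0.330 (edgeR adjusted p = 0.033), basophil-like or mast-like cells from 3.18% ± 1.12 to 0.664% ± 0.125 (edgeR adjusted p = 0.0054) and plasma cell-like cells from 1.58% ± 0.480 to 0.674% ± 0.173 (edgeR adjusted p = 0.023). Neutrophil-like cells were at 1.48% ± 0.0808 against 6.05% ± 4.63 (edgeR adjusted p = 0.042), although the libraries of the groups overlapped (exact two-sided permutation p = 0.4). Cells of 2 unnamed clusters, 1 led by Ppp1r14a and Ccnd1 and 1 by Il22 and Il23r, rose from 0.303% ± 0.0623 to 0.883% ± 0.0661 (edgeR adjusted p = 0.0016). Regulatory T-like cells were at 5.65% ± 0.252 against 3.81% ± 0.544 and monocyte-like cells at 1.96% ± 0.545 against 5.42% ± 2.51 (edgeR adjusted p = 0.0504 for each). Among cells outside the immature myeloid-like, neutrophil-like and erythroid-like classes the CD4 T-like difference was 0.61 and no longer passed (edgeR adjusted p = 0.087). Leaving out 1 library ended the call of the CD4 T-like share in 6 of 9 cases (edgeR adjusted p of up to 0.125), of the CD8 T-like share in 4 (up to 0.0918) and of the neutrophil-like share in 7 (up to 0.127). It also ended the calls of the erythroid-like share in 4 cases (up to 0.1) and of the plasma cell-like share in 3 (up to 0.0969).

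In CD4 T-like cells edgeR called 30 genes with doxorubicin, and DESeq2 342. The edgeR count was 0 without vehicle 3, any 1 doxorubicin library, IMP125 2 or IMP125 3, and 6 without IMP125 1. It was also 0 with only the 6 libraries compared and without genes low in the class. The genes named here come from 1 fit of all 9 libraries. Ccr7, the chemokine receptor for entry into lymphoid tissue, rose from 1014 ± 135 to 1839 ± 164 CPM (log2 fold change 0.86, SE 0.13, edgeR adjusted p = 0.047) and S1pr1, the receptor for egress from it, from 339 ± 24.9 to 554 ± 21 CPM (log2 fold change 0.71, SE 0.11, edgeR adjusted p = 0.047). The highest were Pim1, Il21r, Crip1, Insig1 and Cyp51 (log2 fold changes 0.89 to 1.04, edgeR adjusted p = 0.047). The heat shock genes Hsph1, Bag3 and Dnajb1 were the lowest (log2 fold changes -1.11, -1.06 and -1.0; edgeR adjusted p = 0.047). Cluster 18, whose leading genes include Hspa1b and Hspa1a, held 12.6% to 14.3% of the class with doxorubicin against 30.3% to 32.4% with vehicle. Of 12 naive and memory genes 2 rose, and 3 adjusted over the list alone (median 0.27, camera adjusted p = 0.00025; adjusted p = 0.139 with an estimated correlation). Of 15 cholesterol synthesis genes 3 rose, and 11 adjusted over the list alone (median 0.56, camera adjusted p = 9.4e-11; adjusted p = 0.157 with an estimated correlation). The same 2 lists were called higher in CD8 T-like cells (camera adjusted p = 0.0031 and 4.6e-05; adjusted p = 0.303 for each with an estimated correlation). Camera did not call the exhaustion list in CD4 T-like or CD8 T-like cells (adjusted p = 0.454 and 0.0606) or the type I interferon list in CD4 T-like, CD8 T-like or B-like cells (adjusted p = 0.417, 0.353 and 0.323). Without vehicle 1 the mean of the naive and memory list moved from 0.38 to 0.25 in CD4 T-like and from 0.29 to 0.17 in CD8 T-like cells. Camera called the exhaustion list higher in CD8 T-like cells without vehicle 2, doxorubicin 2, IMP125 2 or IMP125 3 (adjusted p = 0.0254 to 0.0483).

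In B-like cells 5 targets of p53, the transcription factor of the DNA damage response, rose with doxorubicin. Ccng1 rose from 45.4 ± 8.94 to 112 ± 14 CPM (log2 fold change 1.30, SE 0.16, edgeR adjusted p = 0.0073), Bax, which promotes apoptosis, from 135 ± 21.1 to 269 ± 33.4 CPM (log2 fold change 1.00, SE 0.14, edgeR adjusted p = 0.010) and Phlda3 from 0.190 ± 0.194 to 4.09 ± 1.28 CPM (edgeR adjusted p = 0.010). Sesn1, another target, fell from 241 ± 28.5 to 114 ± 12.2 CPM (edgeR adjusted p = 0.024). Of 21 p53 targets 5 rose and 1 fell, and 7 and 1 adjusted over the list alone (camera adjusted p = 8.1e-05; adjusted p = 0.110 with an estimated correlation). Cdkn1a was at 21.5 ± 4.96 against 22.8 ± 16.7 CPM (edgeR adjusted p = 0.95). Of 26 cell cycle genes, among them Cdk1, Ccna2, Birc5 and Aurkb, 6 fell, and 16 adjusted over the list alone (median -1.17, camera adjusted p = 3.2e-06; adjusted p = 0.767 with an estimated correlation). Without genes low in the class, which RNA of other cells can reach, the mean of the cell cycle list turned from -1.2 to 0.0654 (camera adjusted p = 0.939). The immediate early gene Nr4a1 rose from 743 ± 94.7 to 1859 ± 82.9 CPM (edgeR adjusted p = 0.010). Egr1 rose from 86.5 ± 26.6 to 339 ± 64.9 CPM (edgeR adjusted p = 0.021). Both are in the activation list, of which 3 of 10 genes rose (camera adjusted p = 1.6e-05, and 0.305 with an estimated correlation). The list of dissociation and immediate early genes was not higher, at a mean log2 CPM of 8.54, 8.72 and 8.81 in doxorubicin 1, 2 and 3. Vehicle 1, 2 and 3 were at 8.76, 9.09 and 8.85. Atp1b1, Hspb1 and Hsph1 were the lowest genes (log2 fold changes -2.52, -2.18 and -1.77; edgeR adjusted p = 0.0016, 0.024 and 0.017). The clusters of the class shifted as well. Cluster 10, whose leading genes include Hspa1b, Hspa1a and Hsph1, held 4.27% to 9.15% with doxorubicin against 22.8% to 34.6% with vehicle, and cluster 0 69.6% to 76.2% against 5.66% to 36.1%. All 5 primary granule genes fell in B-like cells (camera adjusted p = 0.000105; adjusted p = 0.465 with an estimated correlation). Neutrophil genes were lower in CD4 T-like, CD8 T-like and B-like cells (medians -2.92, -3.21 and -3.15; camera adjusted p = 7.4e-06, 2.1e-07 and 5.7e-06; adjusted p = 0.571, 0.326 and 0.465 with an estimated correlation), and without vehicle 2 their mean in CD8 T-like cells moved from -2.62 to -3.965.

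In neutrophil-like cells, interferon-induced genes were higher with doxorubicin than with vehicle too. The type I interferon list summed to 4950, 3106 and 3698 CPM in doxorubicin 1, 2 and 3. It summed to 334, 1422.5 and 1163 CPM in vehicle 1, 2 and 3. The untreated healthy library, with 67 neutrophil-like cells, was at 4288 CPM, within the range of the doxorubicin libraries. Gbp2 rose from 11.1 ± 5.48 to 276 ± 105 CPM (log2 fold change 4.79, SE 0.57, edgeR adjusted p = 0.0098) and Cd274, the ligand PD-L1, from 48.5 ± 14.4 to 243 ± 23 CPM (log2 fold change 2.33, SE 0.35, edgeR adjusted p = 0.015). Of 21 interferon gamma genes 10 rose, and 19 adjusted over the list alone (median 2.26, camera adjusted p = 1.2e-17; adjusted p = 0.243 with an estimated correlation). Of 26 type I interferon genes 4 rose, and 19 adjusted over the list alone (median 1.68, camera adjusted p = 1.7e-14; adjusted p = 0.257 with an estimated correlation). Nuclear genes of the respiratory chain were called lower (median -0.48, camera adjusted p = 2.9e-14; adjusted p = 0.431 with an estimated correlation), where edgeR called 0 of 77 (20 at an unadjusted p under 0.05; 2 by DESeq2). Without vehicle 1 the mean of the type I list moved from 2.08 to 1.24, and without doxorubicin 3 that of the respiratory chain from -0.50 to -0.78. Bcl2l15, Ifitm6 and the sterol enzyme Fdps were the lowest genes, and Lcn2, a protein of neutrophil granules, fell from 12464 ± 1067 to 4014 ± 1064 CPM (log2 fold changes -3.76, -1.98, -1.72 and -1.63; edgeR adjusted p = 0.015 to 0.029). Cluster 36 held 76.7% of the neutrophil-like cells of vehicle 1 and 0% with doxorubicin, and cluster 27 85.0% to 96.3% with doxorubicin against 0.758% to 61.4% with vehicle.

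Over all genes, doxorubicin against vehicle gave 17 higher and 13 lower in CD4 T-like, 223 and 268 in B-like and 49 and 8 in neutrophil-like cells. In CD8 T-like cells edgeR called 0 genes, where 1342 had an unadjusted p under 0.05 and DESeq2 called 127. DESeq2 called 342, 1120 and 363 in the other 3 classes. The groups did not overlap for 23.9%, 19.3%, 30.4% and 22% of genes in CD4 T-like, CD8 T-like, B-like and neutrophil-like cells, where chance gives 10%. Of the genes called in B-like cells, 140 were at less than 0.5 times their level over all cells, and RNA of other cells can reach such genes. Without doxorubicin 1 the counts were 0, 0, 3 and 5, without doxorubicin 2 they were 0, 0, 49 and 31, and without doxorubicin 3 they were 0, 0, 55 and 25. Without vehicle 1 they were 83, 258, 721 and 17, without vehicle 2 they were 135, 42, 601 and 23, and without vehicle 3 they were 0, 0, 96 and 0. Without an IMP125 library, which shares the estimate of spread, they were 0 to 6, 0 to 3, 433 to 486 and 26 to 181.

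The drugs were then compared with each other. The doses differ in kind, since that of doxorubicin is not given in the labels. The shares of immature myeloid-like cells, 0.0451% ± 0.0210 with IMP125 and 0.00897% ± 0.00865 with doxorubicin, did not differ past the threshold (log2 difference 2.17, SE 1.16, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over classes, adjusted p = 0.24), nor did Hoxb8 (edgeR adjusted p = 0.14) or Il3 (edgeR adjusted p = 0.67). Conventional dendritic-like cells made up a smaller share with IMP125, 1.19% ± 0.293 against 3.03% ± 1.05 (edgeR adjusted p = 0.026), and plasma cell-like cells a larger one, 1.65% ± 0.443 against 0.674% ± 0.173 (edgeR adjusted p = 0.028). The unnamed clusters made up 0.236% ± 0.0245 against 0.883% ± 0.0661 (edgeR adjusted p = 0.00081). The CD4 T-like and CD8 T-like shares did not differ past the threshold (log2 differences -0.47 and -0.49, edgeR adjusted p = 0.26 for each). As shares of all kept barcodes both turned sign (0.13 and 0.10, edgeR adjusted p = 0.722 and 0.759). That total takes in the background barcodes, few with IMP125, and so raises the share of every class there. By that measure the B-like share was called (0.94, edgeR adjusted p = 0.0225) and the conventional dendritic-like share was not (-0.79, edgeR adjusted p = 0.103). Leaving out 1 library ended the call of the conventional dendritic-like share in 3 of 9 cases (edgeR adjusted p of up to 0.0599) and of the plasma cell-like share in 5 (up to 0.133).

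Interferon-stimulated and mitochondrially encoded genes differed between the drugs in all 4 classes. Of 26 type I interferon genes 21 were higher with IMP125 in CD4 T-like, 3 in CD8 T-like, 25 in B-like and 20 in neutrophil-like cells, and 26, 26, 26 and 24 adjusted over the list alone (camera adjusted p = 3.0e-34, 2.2e-30, 5.4e-21 and 2.1e-18; adjusted p = 0.204, 0.326, 0.285 and 0.340 with an estimated correlation). mt-Nd2 was at 2360 ± 285 against 601 ± 35.4 CPM in CD4 T-like cells (log2 fold change 1.97, SE 0.12, edgeR adjusted p = 5.7e-05). Of the 13 mitochondrially encoded mRNAs 8, 8, 9 and 8 were higher in the 4 classes, and 11, 10, 11 and 12 adjusted over the list alone (camera adjusted p = 1.0e-24, 1.9e-19, 1.3e-14 and 1.0e-11; adjusted p = 0.126, 0.195, 0.246 and 0.340 with an estimated correlation). The stress factor Ddit3 was higher with IMP125 in all 3 lymphocyte classes, at 43.1 ± 2.95 against 22.6 ± 1.49 CPM in CD4 T-like, 44.2 ± 0.655 against 25.5 ± 2.84 CPM in CD8 T-like and 57.1 ± 9.94 against 24.8 ± 1.76 CPM in B-like cells (log2 fold changes 0.93, 0.79 and 1.2; edgeR adjusted p = 0.011, 0.046 and 0.0052). Hspe1, a mitochondrial chaperonin, was higher in CD4 T-like cells (273 ± 36.6 against 157 ± 13.1 CPM, edgeR adjusted p = 0.025) and in B-like cells (412 ± 104 against 152 ± 23.8 CPM, edgeR adjusted p = 0.0091).

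In B-like cells the p53 targets Phlda3, Ccng1 and Bax were lower with IMP125 than with doxorubicin (log2 fold changes -4.26, -1.37 and -0.86; edgeR adjusted p = 0.0091, 0.0052 and 0.012), and Fas was higher (log2 fold change 1.47, edgeR adjusted p = 0.0091). Of 26 cell cycle genes 17 were higher, and 24 adjusted over the list alone, with Mki67 at 44.1 ± 31.3 against 4.73 ± 1.62 CPM (edgeR adjusted p = 0.014; camera adjusted p = 6.0e-16; adjusted p = 0.285 with an estimated correlation). Psat1 and Asns, enzymes of amino acid synthesis in the integrated stress response, were higher (log2 fold changes 1.03 and 2.00, edgeR adjusted p = 0.013 and 0.047). In CD4 T-like cells Sytl2, Ifngr2, a chain of the interferon gamma receptor, and S1pr1 were the lowest genes (log2 fold changes -0.74, -0.65 and -0.59; edgeR adjusted p = 0.028, 0.027 and 0.041). The exhaustion list was called higher in CD4 T-like cells (median 0.30, camera adjusted p = 0.017; adjusted p = 0.494 with an estimated correlation) and not in CD8 T-like cells (camera adjusted p = 0.284), with 0 of 14 and 0 of 15 genes called by edgeR (2 and 3 at an unadjusted p under 0.05; 2 and 2 by DESeq2). Its call ended without any 1 of the vehicle libraries, doxorubicin 2, IMP125 1 or IMP125 3 (camera adjusted p = 0.053 to 0.541). In neutrophil-like cells the NF-kB genes Nfkb1, Relb, Sod2 and Nfkb2 were lower with IMP125 (log2 fold changes -1.40 to -1.10; edgeR adjusted p = 0.030 to 0.043). Their list was called lower (camera adjusted p = 2.4e-06; adjusted p = 0.383 with an estimated correlation), and its mean moved from -0.91 to -0.56 without IMP125 2.

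Over all genes, IMP125 against doxorubicin gave 101 higher and 5 lower in CD4 T-like, 20 and 0 in CD8 T-like, 570 and 222 in B-like and 187 and 201 in neutrophil-like cells, and DESeq2 called 358, 308, 1518 and 851. The groups did not overlap for 25.6%, 26.6%, 38.4% and 31.1% of genes, where chance gives 10%. Without doxorubicin 1 the counts were 6, 4, 4 and 37, without doxorubicin 2 they were 8, 4, 19 and 19, and without doxorubicin 3 they were 9, 4, 44 and 908. Without IMP125 1 they were 22, 4, 188 and 45, without IMP125 2 they were 49, 5, 512 and 40, and without IMP125 3 they were 268, 272, 1092 and 899. Without vehicle 1 they were 171, 253, 1915 and 574, without vehicle 2 they were 31, 18, 621 and 210, and without vehicle 3 they were 21, 9, 582 and 166. The background share of the IMP125 libraries, 0.143% to 2.26%, stood apart from that of the doxorubicin libraries, 30.5% to 41.1%, as well.

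The healthy spleen was a single library, so it was set beside the vehicle libraries without a test, and intervals on its values cover counting error only. B-like cells made up 49.8% (95% exact binomial interval 48.7% to 50.9%) against 36.8% ± 7.43 with vehicle. Plasma cell-like cells made up 3.39% (3.01% to 3.80%) against 1.58% ± 0.480, and neutrophil-like cells 0.791% (0.614% to 1.00%) against 6.05% ± 4.63. The plasma cell-like class differed in make-up. Cluster 43, at a median of 1433.5 UMIs, held 258 of its 287 healthy cells and 9, 100 and 26 cells in vehicle 1, 2 and 3. Cluster 35, at a median of 17379 UMIs, held 29 healthy cells against 105, 109 and 140, so the larger healthy share lay in cluster 43. In B-like cells Egr1 was at 352 CPM (95% exact Poisson interval 343 to 361) against 90.9 ± 27 CPM with vehicle and Snx9 at 433 CPM (423 to 443) against 102 ± 68.8 CPM. Ptpn22, a phosphatase that dampens antigen receptor signals, was at 27.8 CPM (25.4 to 30.4) against 182 ± 25.3 CPM, and Fkbp5, a gene induced by glucocorticoids, at 10.6 CPM (9.08 to 12.2) against 68.8 ± 24.4 CPM. In CD4 T-like cells Penk, the precursor of enkephalins, was at 58.6 CPM (52 to 65.8) against 2.46 ± 1.05 CPM, and in CD8 T-like cells Pim1 was at 575 CPM (554 to 596) against 203 ± 18.3 CPM. Cholesterol synthesis genes were higher in the healthy library in B-like cells (median log2 ratio 1.16) and CD4 T-like cells (0.55), in both at the 100th percentile of 10000 random lists matched on level. Cell cycle genes had medians of -0.84 and -0.71, at percentile 0 in both. Markers of other cells were also lower there, with medians of -2.56 and -3.28 for neutrophil and -1.68 and -1.86 for erythroid genes, so RNA of other cells was not excluded for this list. The exhaustion list had a median of 0.02 in CD4 T-like cells (percentile 88.1) and 0.27 in CD8 T-like cells (percentile 99.98). With 5 CPM added to each value instead of 1, the cholesterol medians were 0.80 and 0.38, the cell cycle medians -0.53 and -0.40, and the exhaustion median in CD8 T-like cells was 0.17. Neutrophil-like cells numbered 67 in the healthy library, and their primary granule genes Elane, Mpo, Prtn3 and Ctsg had 0 UMIs, which allows up to 19.5 CPM each, against 267 to 1409 CPM with vehicle. The make-up of this class differed. Cluster 27 held 98.5% of it in the healthy library and 0.758% to 61.4% with vehicle, where cluster 34, which carries markers of immature myeloid cells, held 22.5% to 57.7%. Cluster 36 held 76.7% in vehicle 1.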

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

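All tests in this part were chosen after the results were seen. Transcripts of pancreatic acinar cells, which no comparison used, stood above the level of the healthy and vehicle libraries (highest 17.14 CPM over every barcode) in doxorubicin 1 (138.2 CPM), doxorubicin 2 (2437 CPM), IMP125 1 (5753 CPM) and IMP125 3 (177.5 CPM). Some lists moved in opposite directions in lymphocyte classes and in neutrophil-like cells, and were picked for that. An exact two-sided permutation test of 3 against 3 libraries can give no p below 0.1, so it does not show that the effects differ. For IMP125 against vehicle the primary granule genes moved by -2.33, -2.28 and -2.36 on the log2 scale in CD4 T-like, CD8 T-like and B-like cells and by 1.46 in neutrophil-like cells, differences of -3.79, -3.74 and -3.82 (exact permutation p = 0.1 for each). For doxorubicin against vehicle cholesterol synthesis moved by 0.61, 0.32 and 0.38 in the same lymphocyte classes and by -0.47 in neutrophil-like cells, differences of 1.08, 0.80 and 0.85 (exact permutation p = 0.1 for each).

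Interferon-stimulated genes were higher in all 3 IMP125 libraries. For neutrophil-like cells, RNA of other measured classes would have to supply 63.63% to 117.7% of the UMIs, where markers of those classes showed 15.72% to 28.01%. The ratios in IMP125 1, 2 and 3 were 4.27, 2.27 and 7.49 against a bound of 2 (4.70, 1.99 and 7.24 with markers chosen first, some of which rose with the treatment). The class's own level was taken as the highest vehicle value, 1423 CPM, but doxorubicin and healthy neutrophil-like cells lay at 3106 to 4950 CPM. A higher own level would lower the ratios, so the test does not decide for IMP125 2. The values for IMP125 1 and 3 argue against RNA of other measured classes as the whole cause there. For the lymphocyte classes together, where 15.33% to 49.2% was needed, that cause stays open. The lowest ratio was 1.84, under the bound, in CD8 T-like cells of IMP125 3 (0.37 in CD8 T-like cells with the first markers). In CD4 T-like cells the ratios were 2.09 to 3.43, but 1.61 to 2.19 with the first markers. In B-like cells they were 2.38 to 3.96, and 2.69 to 3.96 with the first markers, which argues against RNA of other measured classes as the whole cause there. Libraries made apart from the others stay open too, since no library outside the IMP125 group held less than 30.5% background barcodes and none within it held more than 2.26%, so treatment and preparation could not be separated. An effect of IMP125 in the animals may account for the genes but stays an untested hypothesis, and UMIs of type I interferon genes themselves numbered 1 to 81 per library, and 69 of the 81 in IMP125 3 lay in 1 barcode of a B-like cell.

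Mitochondrially encoded complex I transcripts were higher in IMP125 lymphocytes. A shift of the whole library would move all classes alike, whereas the log2 ratio was 0.30 in erythroid-like cells against 1.67 in B-like cells, and the gap between those classes was 1.83 ± 0.0827 with IMP125 against 0.453 ± 0.0736 with vehicle (exact two-sided permutation p = 0.1). The make-up of the erythroid-like class differed, and in IMP125 1, 2 and 3 the sum was 1577.7, 2239.1 and 2073.8 CPM in cluster 32 (198 of 1095, 69 of 95 and 64 of 97 cells; vehicle 1632 to 1853.1), 1419.4, 3001.6 and 2445.9 CPM in cluster 26 (642, 13 and 4 cells; vehicle 1058.1 to 1485.7), 1931.8, 594.76 and 736.86 CPM in cluster 28 (184, 10 and 10 cells; vehicle 1372 to 1644.6) and 2275.3, 2387.8 and 3279.7 CPM in cluster 40 (71, 3 and 19 cells; vehicle 741.42 to 1454.8). The IMP125 and vehicle values overlapped in clusters 32, 26 and 28, but all IMP125 values lay above vehicle in cluster 40. The size of the erythroid-like ratio thus depends on the make-up, and for cluster 40 a shift of the whole library stays open. A subset of damaged cells would leave the lower quartile in place, yet the 25th percentile was higher in every IMP125 than in every vehicle library in 3 of 3 classes, and depth per cell would leave no difference, yet at 3000 to 5000 UMIs per cell the share was higher in every IMP125 library in 3 of 3 classes. Libraries made apart, with a background share of at least 30.5% outside the IMP125 group, could also underlie this pattern, and an effect of IMP125 on mitochondria stays an untested hypothesis.

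Primary granule transcripts were lower in the treated lymphocyte classes, where leukaemia cells were also few. RNA of leukaemia cells would leave in B-like cells the proportions of these genes in immature myeloid-like cells, and in the vehicle libraries the largest difference was 7.28 percentage points, within the 10 set for the same source. Elane had 0.2546 and 0.2511, 0.07338 and 0.08629, and 0.4278 and 0.4199 UMIs per cell in B-like and CD4 T-like cells of vehicle 1, 2 and 3, while Ms4a3, on 43 UMIs in B-like cells, lay furthest apart of the 5 genes, at 0.01374 and 0.02965 in vehicle 1. Against background barcodes the largest difference was 11.84 points, between the bounds, so that test did not decide. These values go with RNA of leukaemia cells more than with transcription in the lymphocytes, and no biological explanation was tested.

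The 6 libraries of a comparison can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The genes past the threshold with IMP125 against vehicle numbered 63, 14, 222 and 154 in CD4 T-like, CD8 T-like, B-like and neutrophil-like cells, and at most 0 in each class in the other splits. With doxorubicin against vehicle they numbered 30, 0, 491 and 57, and at most 0, 0, 0 and 1 in the other splits. With IMP125 against doxorubicin they numbered 106, 20, 792 and 388, and at most 2, 3, 1 and 0. Only the real split reached the count in 11 of these 12, and all 10 splits in CD8 T-like cells with doxorubicin against vehicle, where the count was 0. Lists past the threshold numbered 15, 13, 17 and 8 for IMP125 against vehicle, with at most 13, 12, 14 and 14 in the other splits. They numbered 12, 13, 11 and 16 for doxorubicin against vehicle (at most 13, 12, 11 and 15) and 15, 11, 14 and 13 for IMP125 against doxorubicin (at most 15, 11, 13 and 15). The number of splits with as many lists was 1, 1, 1 and 6, then 2, 1, 2 and 1, then 2, 2, 1 and 4.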

How the results depend on the processing

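All gene counts below follow the order CD4 T-like, CD8 T-like, B-like and neutrophil-like cells unless a class is named. The alternatives were chosen before the data were examined, apart from the shares of all kept barcodes and the sums over every kept barcode. With 3 libraries per group and the depth given in the report, changes of 2-fold were often missed in simulated data. For each result below that changed, the cause was not tested, except that fewer libraries or fewer genes enter a fit where a setting leaves them out. The total of all kept barcodes also takes in the background barcodes, few with IMP125, which raises the share of every class there.

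DESeq2 called 331, 309, 793 and 232 genes for IMP125 against vehicle, 342, 127, 1120 and 363 for doxorubicin against vehicle, and 358, 308, 1518 and 851 for IMP125 against doxorubicin. Of 283 values of single genes it reversed 1, Clpx in CD8 T-like cells (-4.75e-05). Many named genes lost their call in other settings: 1146 of 2545 values without 1 library, 120 of 283 with the replicate number as a block, 98 of 282 with only the 6 libraries compared, 68 of 283 without a filter on low counts, 51 of 283 with library size scaling, 32 of 81 with the UMI gate, 17 of 283 with doublets kept, 15 of 227 without genes low in the class and 10 of 283 with stricter cells. Clpx in CD8 T-like cells, close to 0 in all fits, also reversed with the UMI gate (-0.05984), with library size scaling (-0.1563) and without genes low in the class (-0.0008005). The UMI gate gave 26 genes in CD4 T-like cells for IMP125 against vehicle, 6 and 5 in CD4 T-like and CD8 T-like cells for doxorubicin against vehicle, and 10 in CD8 T-like cells between the drugs. Library size scaling gave 19 and 8 genes in CD4 T-like and CD8 T-like cells for IMP125 against vehicle, 129 in neutrophil-like cells for doxorubicin against vehicle, and 6 in CD8 T-like cells between the drugs. With doublets kept, neutrophil-like cells gave 302 genes for doxorubicin against vehicle and 728 between the drugs, and their share with doxorubicin was no longer called (-1.89, edgeR adjusted p = 0.0502). Stricter cells gave 7 genes in CD8 T-like cells between the drugs.

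Without a filter on low counts, IMP125 against vehicle gave 69 and 413 genes in CD8 T-like and neutrophil-like cells, doxorubicin against vehicle 140, 61 and 563 in CD4 T-like, CD8 T-like and neutrophil-like cells, and the drugs 61 and 1134 in CD8 T-like and neutrophil-like cells. With only the 6 libraries compared, IMP125 against vehicle gave 6, 6 and 6 genes in CD4 T-like, CD8 T-like and B-like cells, doxorubicin against vehicle 0 and 180 in CD4 T-like and neutrophil-like cells, and the drugs 198, 1519 and 178 in CD8 T-like, B-like and neutrophil-like cells. Without genes low in the class, doxorubicin against vehicle gave 0, 320 and 134 genes in CD4 T-like, B-like and neutrophil-like cells, and the drugs 13 and 583 in CD8 T-like and neutrophil-like cells. The lists called then numbered 9, 8 and 4 in CD4 T-like, CD8 T-like and neutrophil-like cells for IMP125 against vehicle, 7 and 8 in CD4 T-like and CD8 T-like cells for doxorubicin against vehicle, and 8 in CD4 T-like cells between the drugs. The mean log2 fold changes of T cell effector genes in CD4 T-like cells for IMP125 against vehicle (-0.0166), cell cycle genes in B-like cells for doxorubicin against vehicle (0.06541) and T cell activation genes in CD8 T-like cells between the drugs (0.1339) reversed. With an estimated correlation 0 lists were called by camera in each of the 12 tests of lists.

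The replicate numbers in the titles gave no sign of pairing between the mice. Correlations between libraries of the same number ran from -0.334 to 0.0737, and 8 of 36 were best with their own number. Such correlations, with 3 libraries per group, cannot exclude pairing. With the replicate number as a block, IMP125 against vehicle gave 29 and 68 genes in CD4 T-like and B-like cells. Doxorubicin against vehicle gave 6, 8, 238 and 17, and the drugs 44, 10, 376 and 98. Clpx in CD4 T-like cells reversed with the block (0.008947). The block ended the calls over the whole spleen of Il3 (-4.874, edgeR adjusted p = 0.0934) and Hoxb8 (-5.472, edgeR adjusted p = 0.071) for IMP125 against vehicle, and of the neutrophil-like share with doxorubicin (-1.662, edgeR adjusted p = 0.066).

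As shares of all kept barcodes, B-like, CD4 T-like and CD8 T-like cells differed by 0.9767, 1.092 and 1.368 for IMP125 against vehicle and were called, B-like cells by 0.03503 for doxorubicin against vehicle (reversed), and between the drugs by 0.9417 (called), 0.1303 (reversed) and 0.1041 (reversed). Scaling over classes reversed the B-like share with doxorubicin (0.1175), and outside the immature myeloid-like, neutrophil-like and erythroid-like classes the CD4 T-like share with doxorubicin was 0.6117. For the healthy library a pseudocount of 5 CPM reversed 0 of 32 list medians, moved 18 by more than the SD over the vehicle libraries, and moved 14 by less.

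Without 1 library at a time, IMP125 against vehicle gave 6 to 203, 5 to 209, 7 to 444 and 90 to 198 genes, doxorubicin against vehicle 0 to 135, 0 to 258, 3 to 721 and 0 to 181, and the drugs 6 to 268, 4 to 272, 4 to 1915 and 19 to 908. Lists called in neutrophil-like cells for IMP125 against vehicle numbered 5 to 10. The following changed sign, the B and plasma cell list although it was called: for IMP125 against vehicle Clpx in CD4 T-like (-0.1677 to 0.2832) and CD8 T-like cells (-0.1175 to 0.2094), Clpp in CD8 T-like cells (-0.08461 to 0.02124), the T cell effector list in CD4 T-like (-0.02389 to 0.3202) and CD8 T-like cells (-0.1376 to 0.7205), the T cell exhaustion list in CD8 T-like cells (-0.03963 to 0.2395) and B and plasma cell genes in CD4 T-like cells (-0.1458 to 1.094). The same held for doxorubicin against vehicle in the T cell exhaustion list in CD4 T-like (-0.2332 to 0.306) and the T cell effector list in CD8 T-like cells (-0.617 to 0.24). It also held between the drugs in the T cell activation list in CD8 T-like cells (-0.03877 to 0.07149). The nuclear respiratory chain list in CD4 T-like cells, also called for IMP125 against vehicle, changed sign without vehicle 3.

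Shares without 1 library ran from 0.4694 to 1.053 (CD8 T-like) and -2.266 to -1.145 (neutrophil-like) for IMP125 against vehicle, each called without vehicle 2. For doxorubicin against vehicle they ran from -0.1718 to 0.1158 (B-like), 0.7591 to 0.991 (CD4 T-like), 1.016 to 1.544 (CD8 T-like) and -2.519 to -1.399 (neutrophil-like), and between the drugs from -0.06714 to 0.4709 (neutrophil-like). Il3 ran from -6.028 to -4.326 and Hoxb8 from -6.404 to -5.339 for IMP125 against vehicle, and from -7.41 to -5.54 and -10.19 to -8.704 for doxorubicin against vehicle. The immature myeloid-like share stayed called for each drug against vehicle in all 9 cases, from -7.464 to -6.459 with IMP125 and from -9.934 to -8.625 with doxorubicin.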

Other observations

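The sums of interferon receptor and type I interferon transcripts in this part were tests chosen only after the results were seen. Neutrophil-like cells differed between the drugs in genes of respiration and translation. Of 77 nuclear genes of the respiratory chain 5 were higher with IMP125 than with doxorubicin, and 7 adjusted over the list alone (median log2 fold change 0.64, camera adjusted p = 2.1e-14; adjusted p = 0.383 with an estimated correlation). Uqcrb, a subunit of complex III, was at 207 ± 24.7 against 69.9 ± 43.5 CPM (edgeR adjusted p = 0.034). Mitochondrial ribosomal proteins (median 0.63, camera adjusted p = 5.3e-07; adjusted p = 0.383 with an estimated correlation) and cell cycle genes, of which 11 of 26 were higher (camera adjusted p = 2.3e-14; adjusted p = 0.340 with an estimated correlation), were called too. The granule genes Lcn2 and Ngp were at 10206 ± 2362 against 4014 ± 1064 CPM and 33384 ± 8674 against 12005 ± 5722 CPM (edgeR adjusted p = 0.030 and 0.043). Cluster 27 held 45.3% to 79.8% of the neutrophil-like cells with IMP125 and 85.0% to 96.3% with doxorubicin.

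The 4 genes of interferon receptors summed to 434, 653 and 786 CPM in IMP125 1, 2 and 3, to 660, 633 and 459 CPM with vehicle and to 1073, 1077 and 930 CPM with doxorubicin. UMIs of the 18 type I interferon genes numbered 12, 6 and 81 in IMP125 1, 2 and 3, and 12 of the 81 lay outside 1 barcode.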
